A study of Homo sapiens with 2 samples.

How the data were processed

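DNase-seq was performed on cultured epithelial cells of the immature human epididymis, the duct in which sperm mature after leaving the testis. In this assay DNase I cuts accessible DNA in nuclei, the cut ends are sequenced, and places with many ends are called as DNase-hypersensitive peaks. The labels list 2 samples of 1 group, of which the second was itself a pool of individual samples, and cells received no treatment. Reads were aligned with BWA to hg19 (GRCh37), per the submitters' processing notes. The peak caller, its smoothing and its filters are not given in the sources used here, and extraction and library construction followed the Duke DNase protocol of ENCODE, per the labels' protocols.

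The deposited data analysed here were 1 peak list that the authors made from the samples combined. For each peak it gives the position, a signal value, a −log10 p and a browser score, which were all set by the authors, together with the offset of the summit. The signal is in the authors' own scale, which is not stated, and it is used here only to describe and rank peaks within this list. The deposited −log10 p never fell as the signal rose, started at 1.3 (a p-value of 0.0501) and stopped at 16, a value held by 1551 peaks. The deposited browser score ran from 472 to 1000, and 16206 peaks shared the highest score. The q-value field held only a placeholder. Because the samples were combined before deposition, no value per sample was analysed here, no spread between samples could be computed, and no replicate could be left out. Read depth is unknown, so no counting interval or detection limit is given. Columns of per-sample values not used numbered 0.

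Chromosome Y was left out, which left 132545 peaks on 22 autosomes and X. Coordinates are hg19 and are given 1-based. An annotation or sequence of that build was not used here. The gene table at hand is of GRCh38.p14, and positions were not converted between builds, so peaks were not assigned to genes, promoters, exons or introns, and motifs were not searched. The 17 gene lists and 21 motifs that had been fixed before the data were examined, and the rule for naming genes, could therefore not be applied. The part of that rule that concerns regions was kept: the 10 peaks with the highest signal and the 10 stitched clusters with most peaks are described. Widest peaks, peak-free stretches, dense windows and tests by chromosome were added after the data were seen.

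Peaks up to 12.5 kb apart (end to start) were stitched into regions, and regions with at least 10 peaks were called clusters, as planned. Their number was compared with 100 random placements of the same peak widths on the same chromosome without overlap, after taking out peak-free stretches of at least 1 Mb and the ends of each chromosome outside its first and last peak, which stand in for assembly gaps. Usable lengths behind densities were counted in the same way. These lengths come from the peak list itself, and some of the 59 stretches taken out may be alignable sequence without peaks. Densities and coverage are then too high, most of all where such stretches are many. The smallest p that 100 placements can give is 0.0099. For densities, chromosomes were divided into 5-Mb blocks, of which the 563 with at least 50% of their length usable were kept, holding 130546 peaks. Each chromosome was compared with the others by a two-sided permutation test of 100000 reassignments of blocks to chromosomes, with Benjamini-Hochberg adjustment over 23 chromosomes and a threshold of 0.05 on the adjusted p. Blocks and peaks are parts of one genome map and not biological replicates: these p-values measure variation along the genome and say nothing of variation between individuals or cultures. The strongest 1% of peaks (1325 peaks, signal of at least 0.4086) were compared in the same way, as a share of all peaks in the blocks.

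The code was tested on simulated data. For the clusters, 19 of 20 random lists of 132545 peaks fell within the range of the random placements. The 200 planted clusters added 192.5 clusters (median of 5 lists). Planted peaks lay much closer together than the stitching distance, so recovery of looser clusters was not checked. For the densities, 1 chromosome was called over 10 block sets without a difference, and chromosome 1 was called in 10 of 10 sets when its density was raised 1.5 times. Random lists and block sets without a difference were drawn in the same way as in the tests. They therefore check the code, and not whether blocks are exchangeable. Chromosome 1 has 45 blocks, against 15, 11 and 7 for chromosomes 17, 19 and 22, for which power was not checked. Alternatives were another stitching distance (5 kb), another minimum (5 peaks), the peaks at or above the median signal, a −log10 p of at least 3, placement within 1-Mb windows, merging of peaks less than 500 or 1000 bp apart, blocks of 2 and 10 Mb, and other definitions of the strongest peaks (100 peaks, or 5% of peaks). Alternatives for chromosomes used 20000 permutations. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.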

Results

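Open chromatin was mapped in epididymis epithelial cells to find candidate cis-regulatory elements, the stretches of DNA through which genes active in this epithelium are controlled. The map combined 2 DNase-seq samples of 1 group into a single list of 132545 peaks on 23 chromosomes. The peaks covered 61.5 Mb, or 2.21% of the 2781 Mb that remained after chromosome ends without peaks and peak-free stretches of at least 1 Mb were taken out, at 47.7 peaks per Mb. Neighbouring peaks did not overlap (0 cases). Sequencing depth per sample is unknown, and all values below are the authors' single values for the combined samples, without a replicate error.

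The list ran from many weak, narrow sites to a small number of strong, broad ones. The median peak was 352 bp wide (quartiles 221 and 549 bp) with a signal of 0.0636 (quartiles 0.0434 and 0.111). The signal spanned a 31.05-fold range, from 0.0333 at the list's floor to 1.0339. The strongest 10% of peaks held 30.7% of the summed signal. Only 54311 peaks reached a −log10 p of 3. Width and signal went together across peaks (Spearman's rho = 0.91, peaks not being independent replicates). Median signal was 0.0348 in the narrowest decile, with a median width of 97 bp, and 0.2189 in the widest decile, with a median width of 1268 bp. The summit lay near the middle of most peaks, at a median of 0.479 of the width. How the caller set the ends of a peak is not given in the sources used here.

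**Figure D1:**
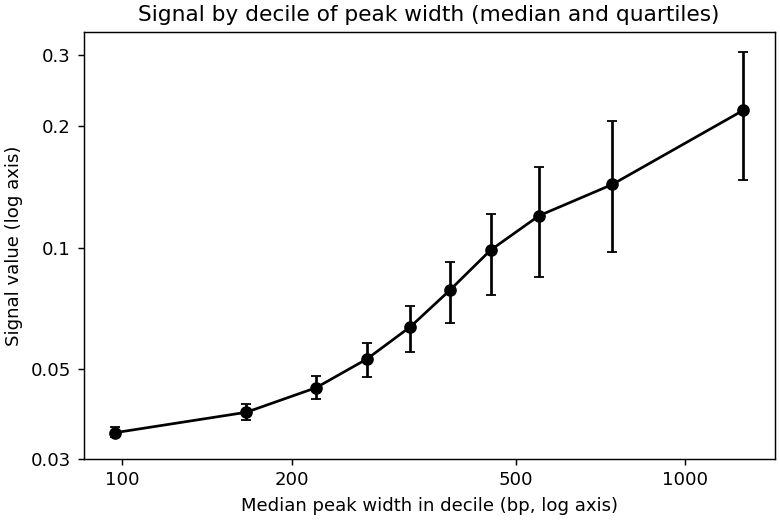
Signal value of DNase peaks (vertical, log axis) against the median width of each decile of peak width (horizontal, bp, log axis), with points at the median and bars from the lower to the upper quartile of peaks. The median climbs from 0.0348 in the narrowest decile to 0.2189 in the widest.

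The strongest single site lay on chromosome X at 149736469 to 149737871, with a signal of 1.0339 over 1403 bp. The next 3 were also on X, at 53110368 to 53112334 (signal 0.918), 149105969 to 149109172 (0.911) and 125714798 to 125715509 (0.898). The last of these was narrow for its strength, at 712 bp, and its nearest neighbouring peak was 11739 bp away. The strongest autosomal site was on chromosome 20 at 62272291 to 62273811, with a signal of 0.876. The remaining 5 of the 10 strongest lay on X at 44731364 to 44733606 (0.867), on 3 at 51421663 to 51423406 (0.851), on X at 63422674 to 63426625 (0.850), on 2 at 11294788 to 11296163 (0.829) and on 7 at 1498034 to 1499921 (0.803). All 10 shared the highest −log10 p of 16, so that value does not rank them.

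Broad open regions were rare. Of all peaks, 11495 (8.67%) were wider than 1000 bp, 1498 (1.13%) wider than 2000 bp and 46 wider than 4000 bp. Peaks over 2000 bp had a median signal of 0.283, against 0.0629 for the others. The widest peak, 6709 bp on chromosome 10 at 134597678 to 134604386, had a signal of only 0.101 and a −log10 p of 4.01. The second widest, 6637 bp on chromosome 7 at 1703520 to 1710156, had a signal of 0.187. The third, 6500 bp on chromosome 10 at 77158391 to 77164890, was stronger, with a signal of 0.493 and a −log10 p of 16. A peak on chromosome 6 at 166073601 to 166078314 combined breadth and strength, with 4714 bp and a signal of 0.726.

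Open chromatin was spread unevenly over the chromosomes. Chromosomes 17, 19 and 22 were denser in peaks than the rest, and chromosomes 4 and X were sparser. Chromosome 22 held 83.4 peaks per Mb, 1.76 times the density of the other chromosomes (adjusted p = 0.0167, permutation test over blocks). In the same permutation test, chromosome 19 held 81.0 peaks per Mb (1.72 times, adjusted p = 0.00293) and chromosome 17 held 76.3 (1.63 times, adjusted p = 0.00293). Chromosome 4 held 34.0 peaks per Mb (0.698 times the others, adjusted p = 0.00046) and X held 35.1 (0.724 times, adjusted p = 0.00293), by permutation. Densities were not adjusted for the number of copies of each chromosome per cell, which for X differs from the autosomes in male cells. Peak-free stretches of at least 1 Mb, and blocks made mostly of them, were left out. A chromosome with many of them may be sparser than stated. The densest chromosome exceeded the sparsest by 2.45 times. Density also varied widely within chromosomes, at 80.3 ± 35.5 peaks per Mb on chromosome 19 (SD, n = 11 blocks) and 33.8 ± 16.6 on chromosome 4 (SD, n = 37 blocks). The other 18 chromosomes did not pass the threshold. Chromosome 22 rests on 7 blocks and lost its call with 10-Mb blocks, at a ratio of 1.83 (adjusted p = 0.0913 by the same permutation test). With 10-Mb blocks the adjusted permutation p also rose to 0.0234 for chromosomes 4, 17 and X and to 0.0253 for 19. The test treats blocks as exchangeable and does not account for likeness of neighbouring blocks, so its p-values depend on block length.

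**Figure D2:**
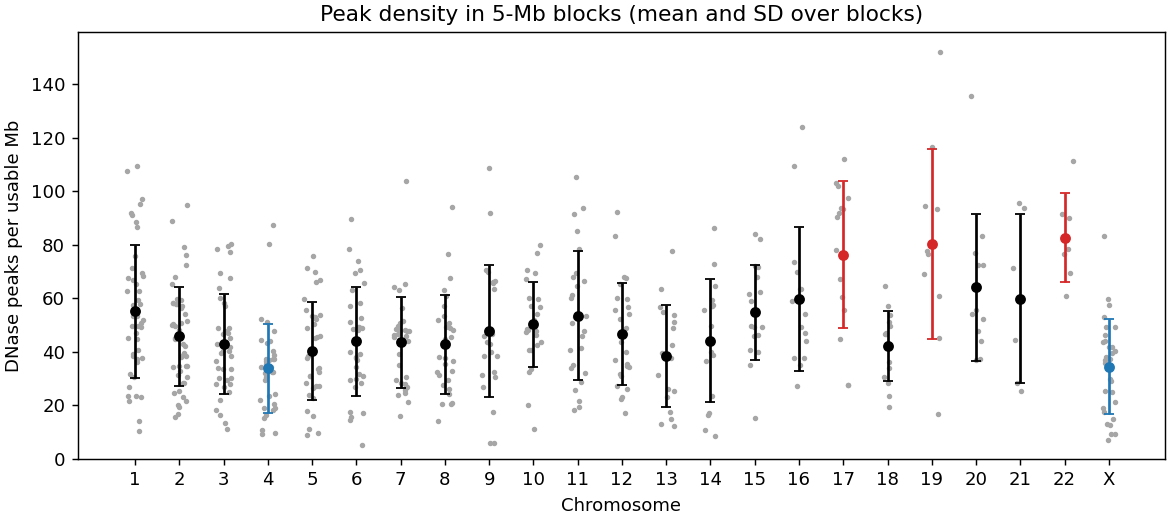
DNase peaks per usable Mb (vertical) in 5-Mb blocks (grey dots) of each chromosome (horizontal), with the mean and SD over the blocks of a chromosome. Chromosomes denser than the rest (17, 19 and 22) are red and those sparser (4 and X) are blue, at an adjusted p under 0.05.

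The whole megabase with most peaks was on chromosome 19 from 1000001 to 2000000, with 173 peaks. The megabase before it on chromosome 19 held 144 peaks, or 196 per Mb when its length is counted from its first peak (0.733 Mb). X from 152000001 to 153000000 held 165 peaks, although X as a whole was among the sparse chromosomes. Chromosome 17 from 48000001 to 49000000 held 161 peaks, and chromosome 9 from 139000001 to 140000000 held 160. The median signals of these 5 windows were, in this order, 0.0709, 0.0642, 0.0496, 0.0654 and 0.0564, so that density and strength did not go together in each of them: on X and 9 the median was below that of the whole list.

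At the other end, 59 stretches of at least 1 Mb between neighbouring peaks held no peak and made up 166 Mb. The longest of these ran on chromosome 1 from 121281267 to 143646122 (22.4 Mb), on 9 from 47185688 to 65839350 (18.7 Mb) and on 16 from 34625954 to 46588293 (11.96 Mb). The next among those between peaks were on 11 from 50129176 to 56457674 (6.33 Mb) and on 7 from 57928656 to 62490515 (4.56 Mb). In addition, chromosomes 15, 14, 13, 22 and 21 held no peak in their first 20.2, 19.4, 19.2, 16.2 and 9.83 Mb. A list of peaks does not tell sequence without open chromatin from sequence to which reads could not be aligned, and an annotation of assembly gaps was not used here.

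The strongest sites were distributed differently from the list as a whole. X held 3.83% of all peaks but 7.85% of the strongest 1% (104 of 1325). These values and those below are shares of peaks and not densities per Mb. X was itself sparse in peaks, at 0.724 times the density of the others, which raises its share of strong peaks relative to a count per Mb. Within the blocks, 2.04% of the peaks on X belonged to the strongest 1%, against 0.943% on the other chromosomes, a ratio of 2.17 (adjusted p = 0.00598, permutation test over blocks). Chromosome 19 was also richer in such peaks, at 2.30% against 0.941% (ratio 2.44, adjusted permutation p = 0.0385). Chromosomes 5 and 12 were poorer, at 0.589% (ratio 0.584, adjusted p = 0.026) and 0.508% (ratio 0.503, adjusted permutation p = 0.019). X and 19 differed in the bulk of their peaks: median signal was 0.0584 on X, the lowest of the 23 chromosomes, and 0.0752 on 19, the highest. On X the signal lay below that of every autosome at the 10th, 25th and 50th percentiles and above every autosome at the 99th percentile, where it was 0.504 against an autosomal range of 0.370 to 0.477. The calls for 19, 5 and 12 did not hold in 4, 3 and 2 of 6 alternatives, with adjusted permutation p up to 0.839, 0.839 and 0.742 for the strongest 100 peaks. The alternatives by block length and by stricter list kept the same strongest 1% of peaks, so they are not independent of each other. Where its call was lost, the ratio for 19 was 1.95 to 2.39. The ratio for 5 was 0.582 with 10-Mb blocks and 0.573 for the strongest 100 peaks, and that for 12 was 0.449 for the strongest 100. For the strongest 5% of peaks the ratios for 5 and 12 were nearer to 1, at 0.804 and 0.915. The call for X depended on how strong peaks were defined, and it was not met for the strongest 5% of peaks (ratio 1.14, adjusted permutation p = 0.545) or the strongest 100 (ratio 4.61, adjusted p = 0.219, with 15 peaks on X).

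**Figure D3:**
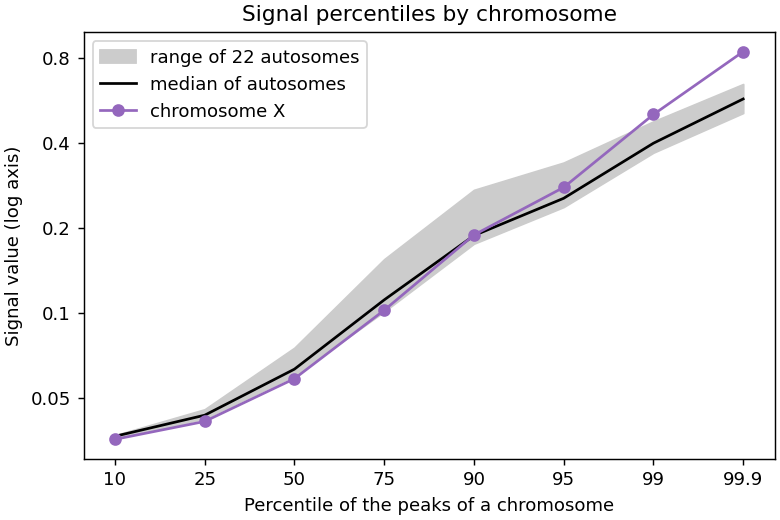
Signal value (vertical, log axis) at percentiles of the peaks of a chromosome (horizontal), for chromosome X (purple), the median of the autosomes (black) and the range of the 22 autosomes (grey band). X runs below the band up to the median, at 0.0584, and above it at the 99th percentile, at 0.504.

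Peaks were grouped along the genome. The median gap between neighbouring peaks was 8.31 kb, against 13.7 to 13.9 kb in 100 random placements. Gaps under 1 kb made up 14.8% of all gaps, against a mean of 4.99% at random, and 18.9% of peaks stood alone after stitching, against 29.0% at random. The stitched map held 1495 clusters of at least 10 peaks, against a mean of 159 (range 136 to 183) in the random placements, a ratio of 9.42 (one-sided permutation test by placement, p = 0.0099, the smallest that 100 placements can give). Against placements that kept the number of peaks in each 1-Mb window, with a mean of 807 clusters, the ratio was 1.85. The clusters held 15.9% of all peaks on 3.01% of the searched span, and their median span was 51.7 kb. The largest held 55 peaks, and the largest in any random placement held 32. Clusters were most frequent on chromosomes 22, 19 and 17, at 20.8, 18.2 and 15.8 per 10 Mb, and least frequent on chromosome 4, at 1.68.

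**Figure D4:**
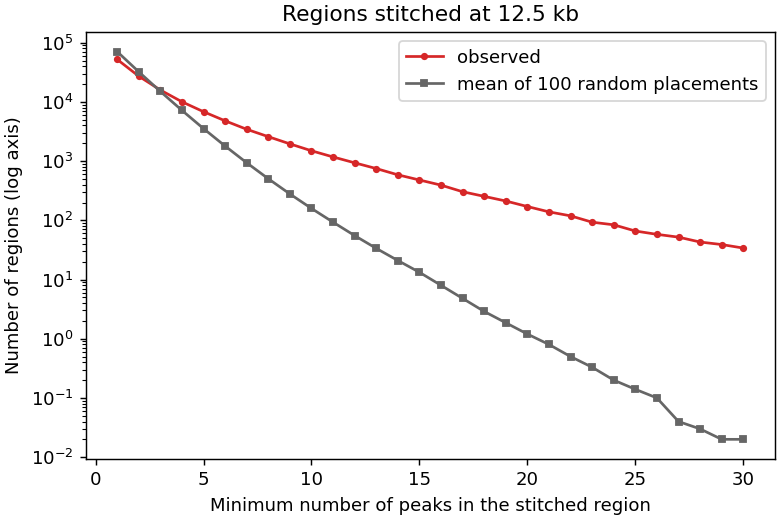
Number of stitched regions (vertical, log axis) with at least the given number of peaks (horizontal) in the list (red) and as the mean of 100 random placements (grey). At a minimum of 10 peaks the list holds 1495 regions and the random placements a mean of 159.

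The cluster with most peaks lay on chromosome 16 from 1047311 to 1249706, with 55 peaks over 202 kb and a highest signal of 0.279. The second lay on chromosome 7 from 27120452 to 27250448, with 53 peaks packed into 130 kb. Its peaks were denser than those of the other 9 of the largest 10 clusters, at 4.08 per 10 kb, and covered 19.3% of its length, but its median signal, 0.0481, was low. The third, on chromosome 16 from 672172 to 864022, held 52 peaks and the highest summed signal of the 10, 5.94. A cluster on chromosome 9 from 137208263 to 137348678 held 44 peaks, and one on chromosome 17 from 48104165 to 48256137 held 41 with the highest median signal of the 10, 0.107. On chromosome 17 from 36053362 to 36209559, 39 peaks reached at most 0.203. The remaining 4 each held 37 peaks, on chromosome 8 from 21966261 to 22113400, on 20 from 62066201 to 62191273, on X from 152700204 to 152820607 and on 12 from 132969967 to 133101934. The cluster on X contained a peak with a signal of 0.734, the strongest in these 10 clusters.

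**Figure D5:**
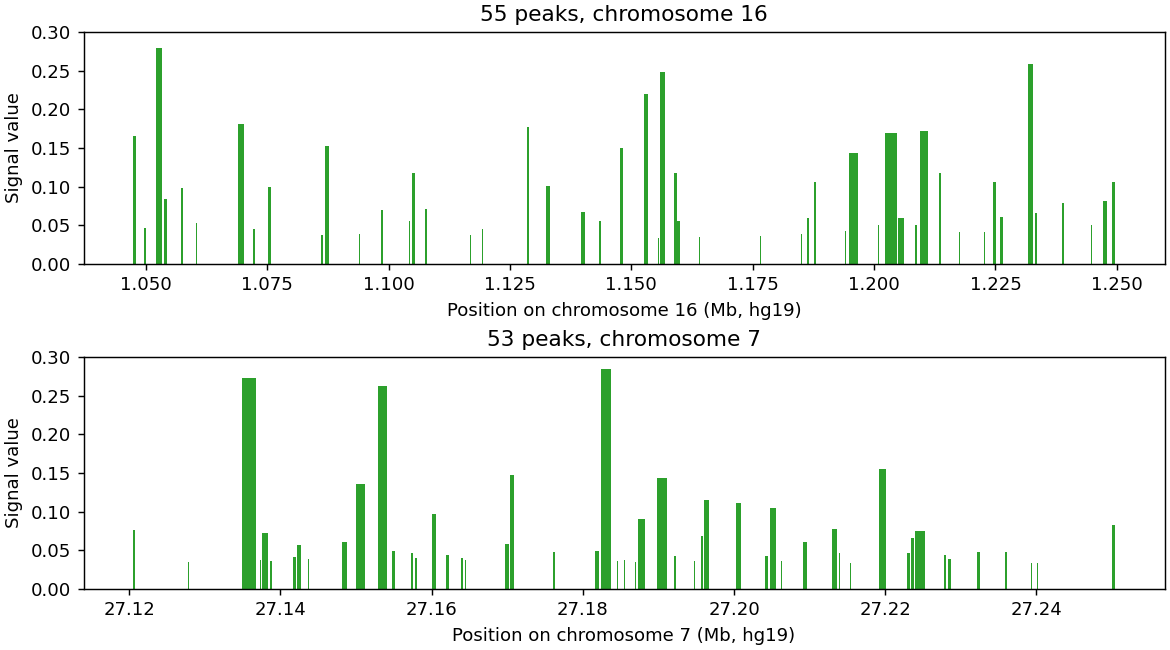
Positions (horizontal, Mb, hg19) and signal values (vertical) of the peaks in the clusters with most peaks, on chromosome 16 (55 peaks, upper panel) and chromosome 7 (53 peaks, lower panel), with each bar as wide as its peak. In both, a few peaks reach over 0.2 and most stay below 0.1.

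Clustered peaks were close in strength to lone ones. Their median signal was 0.0634 (quartiles 0.0425 and 0.116, 21122 peaks), against 0.0615 (quartiles 0.0435 and 0.107, 25045 peaks) for peaks alone, and their median width was 388 bp against 323 bp. The strongest 1% made up 1.05% of clustered and 1.09% of lone peaks, and 202 of the 1495 clusters contained such a peak. No test across peaks is given for these values, since peaks are not replicates.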

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

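The number of clusters and the size of its excess over random placement depended on the definition and on the placement. The number was above all 100 placements in each of the 8 alternatives, 5 of them chosen after seeing the data. It was 235 with a stitching distance of 5 kb, 6827 with a minimum of 5 peaks, 122 among the peaks at or above the median signal and 40 at a −log10 p of at least 3. Merging peaks less than 1000 bp apart left 768, and merging below 500 bp 1037. The ratio to random placement ran from 1.85, with placement within 1-Mb windows, to 294, with 5 kb, where random placement gave a mean of 0.8. The list itself fell from 132545 to 66285 peaks at or above the median signal and 54311 at a −log10 p of 3. All chromosome tests and their alternatives were chosen after seeing the data. With 2-Mb blocks 5 chromosomes were denser and 4 sparser, in place of 3 and 2. Only 1 chromosome was richer in the strongest peaks with 10-Mb blocks, at or above the median signal, at a −log10 p of 3 or for the strongest 5%. It was chromosome 19 for the strongest 5% and X in the other settings. Only 1 was poorer with 10-Mb blocks (chromosome 12) or for the strongest 5%. For the strongest 5% it was neither 5 nor 12, which had adjusted permutation p of 0.166 and 0.594. For the strongest 100 peaks 0 chromosomes were richer and 0 poorer by the permutation test, with 2 at an unadjusted p under 0.05. The ratio for chromosome 19 kept its direction and lost its call in 4 of 6 alternatives, for 5 in 3, and for 12 and X in 2 each. For density, calls on 4, 17, 19 and X held in all 4 alternatives, and that on 22 was lost with 10-Mb blocks. The 10-Mb blocks also gave the weakest calls on 4, 17, 19 and X, with adjusted permutation p up to 0.0253. The cause of these changes was not tested. The other 18 of the 21 alternatives listed beforehand, which concern promoters, gene lists and motifs, were not run because an hg19 annotation and sequence were not used here. No replicate could be left out of a combined list. No paired analysis was possible because there is 1 group and 1 combined list. Depth is unknown, so how far it limits the weak peaks near the floor cannot be stated.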

Other observations

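The tests in this part were chosen after the peak list had been seen, and for the clusters and the scale of signal on X also after a first look at the values they measure. Over 7722 pairs less than 300 bp apart, the signals of both peaks were negatively correlated across pairs (Spearman's rho = −0.15), below the range of −0.02 to 0.04 from 100 permutations of signal within chromosomes. The stronger peak of such a pair was a median of 2.04 times the weaker, against 1.76 times over all neighbouring pairs and 1.72 to 1.83 times in the other distance ranges. From 300 to 1000 bp rho was −0.06, from 1000 to 3000 bp it lay within the permuted range, and from 30000 to 100000 bp it was 0.04, above the permuted range of −0.01 to 0.02. Pairs are not independent, so these values describe the map only. The strongest 1% of peaks had a neighbour within 1 kb in 38.4% of cases, against 26.2% of other peaks. Gaps between neighbours were most frequent at 200 to 250 bp (1688 gaps), against 403 at 0 to 50 bp and 636 at 950 to 1000 bp.

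Some dense clusters held no strong peak. In 50 of the 1495 clusters each peak was below the list's upper quartile of signal, within the 30 to 56 found when signals were permuted, so their number was not unusual. The 3 with most peaks were on chromosome 18 from 55844350 to 55937543 (24 peaks, highest signal 0.109), on 7 from 1264156 to 1291117 (20 peaks, 0.0787) and on 7 from 63011889 to 63044486 (19 peaks, 0.0615). The clusters on 7 were tightly packed, at 7.42 and 5.83 peaks per 10 kb. The second of them began shortly after a peak-free stretch of 4.56 Mb on 7, which ended at 62490515. Another weak cluster, with 15 peaks from 57064102 to 57088893, lay before the start of that stretch at 57928656. Whether reads align uniquely in these regions was not tested.

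Peaks per Mb varied between chromosomes, and a candidate explanation is gene density. Protein-coding genes were counted by chromosome name only, 19974 in all, from a GRCh38.p14 gene table, without its coordinates, and divided by the usable length. Across 23 chromosomes peak density correlated with gene density (Pearson's r = 0.84, Spearman's rho = 0.90, permutation p = 1e-05 for each, the smallest the permutations can give, and 1.5e-05 adjusted over 3 relations). Without chromosomes 19 and 17, farthest from the median gene density, r was 0.86. Median signal correlated with gene density too (r = 0.93, rho = 0.84, permutation p = 1e-05 for each, 1.5e-05 adjusted), with r = 0.83 without those chromosomes. The share of the strongest 1% did not hold: r was 0.66 (permutation p = 0.00382, the same after adjustment) and rho 0.28 (p = 0.198), and r fell to 0.24 without 19 and 17, so it rests on them. Peak density and gene density share a denominator, the usable length, which was itself taken from the peak list. Permutation of the finished densities does not account for this. Sequence composition and the share of alignable sequence also differ between chromosomes and were not tested.

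The excess of clusters over random placement (1495 against a mean of 159) might arise from dense megabases or from single regions that the caller split. Against placements that keep the number of peaks in each 1-Mb window the ratio was 1.85, above all 100, which argues against megabase density as the whole cause; those placements gave a mean of 807. After peaks less than 1000 bp apart were merged, 768 clusters remained, 15.5 times random placement, and 2.51 times when both corrections were applied together. Density differences below a megabase stay open, among them gene-rich stretches and uneven alignability. The biological reading, domains of regulatory DNA, was not tested.

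The excess of the strongest peaks on X, as a share of its peaks, might come from a single region, from reads piled up over collapsed repeats or from the way signal was scaled. A single region is argued against: 25 of the 30 blocks of X held such peaks, and without the block that holds most of them (16 of 103, 150000001 to 155000000) the share was 1.88%, still over 0.943% elsewhere. Collapsed repeats were assumed to give narrow peaks, which was not checked. The strong X peaks were narrower than autosomal peaks of equal signal by a median of 0.17 on the log2 scale (difference −0.17, 95% bootstrap interval −0.31 to −0.05), too little to decide. One scale factor for X stays open as well. X signals were divided by 1.38 and the list's floor was applied again, which left 3349 of 5076 X peaks. This brought the 99th percentile of X to that of the autosomes. The median of the X peaks left was 0.942 times that of the autosomes (0.0595, interval 0.0583 to 0.0610). That median was just below the autosomal range of 0.0599 to 0.0752, with an interval that reached into the range. The upper quartile of the X peaks left was 0.1001 (interval 0.0972 to 0.1047). It was likewise just below the lowest upper quartile of the autosomes, 0.1011. Both values describe only the peaks left above the floor. No biological explanation was tested, since the design has 1 group. The number of copies of X per cell was not taken into account.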
